A study of Mus musculus with 2 samples.

How the data were processed

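The data are 2 bulk RNA-seq libraries of splenic CD8+ T cells from wild-type mice, 1 cultured for 8 h in complete RPMI 1640 and 1 in RPMI 1640 without methionine. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with either a whole-RNA or an mRNA kit, without saying which kit made which library. The labels do not say whether the cells of both cultures came from the same animals or how the CD8+ T cells were isolated. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, the annotation release and the use of strand in counting are not given in the sources used here. The deposited table gives raw counts per gene for 54532 Ensembl gene identifiers, as whole numbers with no scaling. The file header names 1 column with a misspelt form of the word control and 1 column beginning with Met, which were matched to the complete and methionine-free samples by the samples' titles and descriptions. The column names carry different numbers, 2 and 1, and the labels do not say whether the cultures are paired. The table holds no fold changes or p-values of the authors.

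Gene symbols, biotypes and coordinates came from GENCODE M21, an annotation of GRCm38, the same assembly as mm10; coordinates are 1-based and span the whole gene, whose reads are counted over the gene as annotated by the authors. Of the identifiers, 54495 matched and 37 did not; those 37 held 0.00742% of the complete-medium counts and 0.00910% of the methionine-free counts. Of all genes, 21114 had a count in at least 1 library.

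Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, which gave factors of 1.003 and 0.997. The log2 difference was computed in Python 3.11.15 as methionine-free minus complete medium, with a prior count of 0.5 scaled to library size, over 13041 genes with a mean of at least 10 counts in the 2 libraries. A printed fold is the ratio of scaled counts without the prior count. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts, computed with scipy 1.17.1. Reads were taken as deposited, with no molecular identifiers named, so intervals and floors cover counting error only. A single count was worth 0.0681 CPM in complete medium and 0.0510 CPM without methionine, and a gene with 0 counts was set against a floor of 3 counts, 0.204 and 0.153 CPM. With 1 library per medium there was no test across replicates, and genes were called higher or lower by size alone, at 2-fold over all genes and at 1.5-fold for members of lists.

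Before the data were examined, 33 gene lists were fixed, covering amino acid and methionine metabolism, methylation enzymes, T cell states, cell division, energy and lipid metabolism, stress responses, other cell types and RNAs that tell library kinds apart. A list's median log2 difference was placed as a percentile among the medians of 10000 random lists of the same size, drawn from 20 bins of mean count; this describes these 2 libraries only and is not a test of the media. The genes to be named were also fixed by a rule. It took Trnp1, Cd8a and Cd8b1, then the 12 highest and 12 lowest log2 differences among genes with a mean of at least 50 counts, without predicted genes, pseudogenes, histone genes and variable segments. It also took the 4 members of each list with the largest absolute difference, Mat2a, Ahcy, Mtr, Cth and Mtap of the methionine list, and Atf4, Asns, Ddit3, Trib3 and Chac1 of the amino acid response list. The rule named 157 genes, of which the text leaves some out; a few are not reported here. Genes named outside it in the report were chosen after their values were seen: Eef1a1, Mki67, Top2a, Mcm2, Ccnd2, Pkm, Ldha, the main Aldoa identifier, Gapdh, Phgdh, Psph, Ppp1r15a, Il2ra, Ifng, Gzmb, Tgfb1, Cd4, Dnmt3a, Srp54a, Srp54c, Ighm, Gas5, Malat1, Neat1 and Kcnq1ot1. The genes named outside it in the closing section were likewise chosen after their values were seen, among them Scd2, Fads1, Fasn, Dctpp1, Cad, Cd83, Icam1, Nfkb2, Tnfsf11, Tnfsf8, Cd70, H2-K1, Psmb10, Myc, Zbtb46, Ciita, Cst3, H2-Ab1, H2-Eb1, Sirpa, Tmem176b, Tyrobp, Lyz2, Fcer1g, Cd74, Ctss, Ddit4, Jdp2, Stc2, Snhg14 and Zfas1. The colours of the amino acid response plot follow the kind of protein encoded, assigned after the values were seen.

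The steps were tested on simulated libraries of the same depths, with 200 genes changed by known folds, over 13082 genes past the filter. All 50 genes raised 4-fold and all 45 measured genes lowered 4-fold were past 2-fold in the right direction. Of the 50 genes raised 1.5-fold, 40.0% were past 1.5-fold, as were 54.2% of the 48 lowered by the same factor. Of the unchanged genes, 0.776% were past 2-fold. The intervals held the true fold for 95.5% of genes, and 5% of 200 random lists lay outside the central 95% of their own random lists. The simulation held counting noise only, so it says nothing of differences between cultures.

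Alternatives planned before the data were examined were DESeq2 1.42.0 size factors, total counts without the TMM factor, a prior count of 2, a mean of at least 100 counts, no minimum count, other fold thresholds, removal of RNAs without a poly(A) tail with mitochondrial and ribosomal protein genes, protein-coding genes with a named symbol only, and random lists not matched on expression. Alternatives added after seeing the data were thinning the methionine-free library to the total of the other, removing the trend with GC content and transcript length in 10 by 10 bins, and leaving cell cycle members out of the other lists. GC content and length were known for 99.9% of the genes compared.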

Results

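Gene expression was measured in CD8+ T cells isolated from the spleens of wild-type mice and cultured for 8 h in complete RPMI 1640 or in RPMI 1640 without methionine. Methionine is an essential amino acid and the precursor of S-adenosylmethionine, the methyl donor of most methyltransferases. There was 1 bulk RNA-seq library per medium, so no difference below has a replicate check and no p-value is given. The column names of the table carry the numbers 2 for complete medium and 1 for methionine-free medium, and whether these number further libraries is not given in the sources used here. The complete-medium library held 14646527 counts over 19110 genes with at least 1 count, and the methionine-free library held 19647681 counts over 18374 genes. The gene with the most counts, the elongation factor gene Eef1a1, took 1.68% of the complete-medium counts and 2.28% of the methionine-free counts. Folds are ratios of TMM-scaled read counts between the 2 libraries. Levels are in CPM, counts per 1000000 scaled counts of a library. The 95% interval after a fold is an exact conditional interval that covers counting error only, not the spread between cultures or animals.

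The comparison asks which transcripts of CD8+ T cells differed after 8 h without methionine. The cell cycle list had the lowest median of the 33 fixed lists. Of the 38 measured members of the cell cycle list, 37 were at least 1.5-fold lower in the methionine-free library and none was at least 1.5-fold higher. Ccna2, which encodes cyclin A2, was 40.1-fold lower (31.1 to 52.7), from 125 to 3.11 CPM. Mat2a, which encodes the catalytic subunit of the enzyme that makes S-adenosylmethionine from methionine, was 4.97-fold higher (4.82 to 5.13), from 312 to 1549 CPM. Transcripts of the stress-response transcription factors Ddit3 and Atf5 were 5.80-fold and 5.36-fold higher, while those of cholesterol synthesis and glycolysis lay lower.

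Of 13041 genes with a mean of at least 10 counts, 756 were at least 2-fold higher without methionine and 1211 at least 2-fold lower. The counting interval excluded a ratio of 1 for 683 of the higher and 1162 of the lower genes. At 4-fold, 120 genes were higher and 389 lower, and at 16-fold 13 were higher and 74 lower. The median log2 difference over all 13041 genes was 0.04. These counts rest on size alone and describe these 2 libraries. Without a minimum count, 3333 genes were at least 2-fold higher and 4877 lower, and with a mean of at least 100 counts 264 were higher and 576 lower. The genes added without a minimum have a mean below 10 counts, where a few counts can make 2-fold. They are not read as changed.

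**Figure D1:**
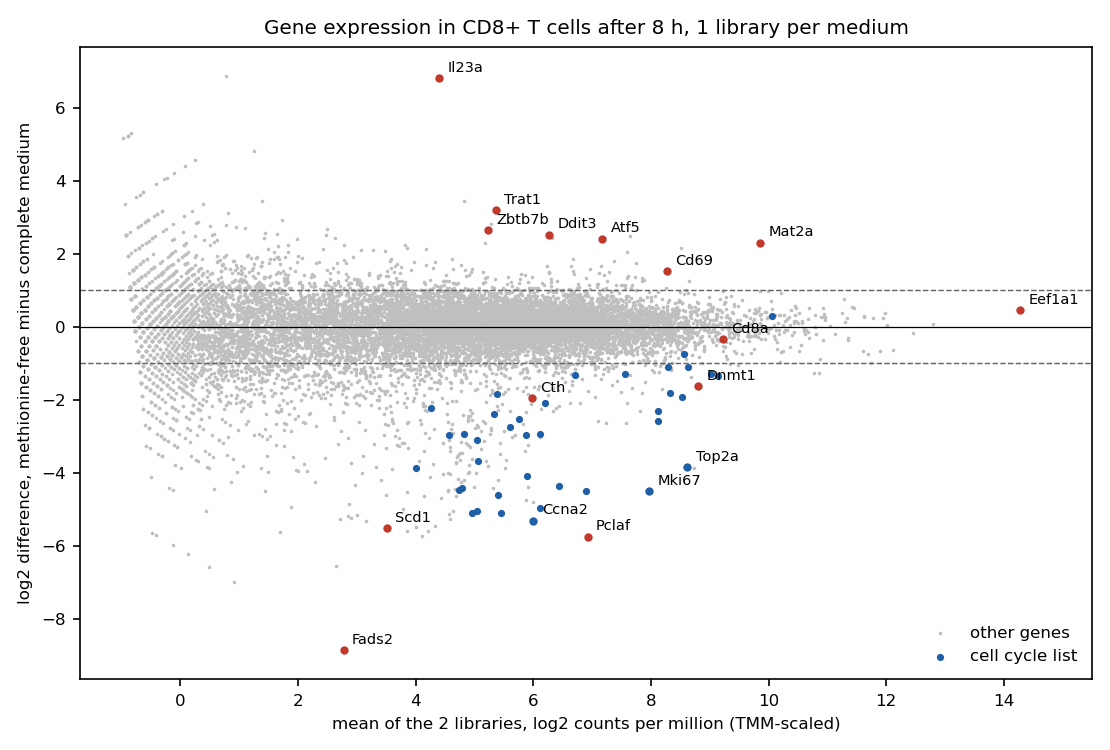
Each point is 1 of the 13041 genes, with the mean level of the 2 libraries on the x axis (log2 CPM) and the log2 difference, methionine-free minus complete medium, on the y axis; blue points are the cell cycle list, red points are other named genes, and dashed lines mark 2-fold. Of the 38 blue points 37 lie below 0, and Mat2a and Ddit3 lie above the upper dashed line; the position of Fads2, with 0 counts without methionine, depends on the prior count.

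The median log2 difference of the cell cycle list was -2.94, lower than that of every one of 10000 random lists of the same size matched on expression. The mitotic genes Cenpf, Bub1 and Birc5 were 35.0-fold, 34.7-fold and 33.7-fold lower. Mki67, the gene of the proliferation marker Ki-67, went from 479 to 21 CPM, and Top2a, the DNA topoisomerase of dividing cells, from 736 to 51.2 CPM. The DNA replication helicase gene Mcm2 was 1.67-fold lower (1.61 to 1.73), the smallest difference among the 37 lower members. Ccnd2, which encodes cyclin D2, was the exception, at 960 CPM in complete medium and 1181 CPM without methionine. Ccna2 was also among the 12 genes with the lowest log2 differences. Of the others, Pclaf, a PCNA-binding factor gene on chromosome 9 (65890237 to 65903266, plus strand), was 54.3-fold lower (43.9 to 68.1). Pimreg had 183 counts in complete medium and 2 without methionine, a ratio of 122 (33.3 to 1016). Kif18b, Anln, Pbk and Nuf2 were between 39.7-fold and 50.9-fold lower. Pclaf and Ccna2 overlap Trip4 and Exosc9 on the opposite strand, and whether the counting used strand is not given in the sources used here.

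Within the methionine cycle, salvage and linked folate list, 3 of the 28 measured members were at least 1.5-fold higher and 6 at least 1.5-fold lower, with a median of -0.08 at percentile 11.3 of the matched random lists. At 2-fold, 1 was higher and 3 lower. Mat2a (ENSMUSG00000053907, chromosome 6, 72432799 to 72439558, minus strand) went from 4576 to 30360 counts. Mtr, which encodes methionine synthase, stayed at a ratio whose interval held 1, with 83.1 CPM in complete medium and 79.8 CPM without methionine. Cth, the cystathionine gamma-lyase gene of transsulfuration, was 3.87-fold lower (3.50 to 4.29). Cbs, the other transsulfuration enzyme gene, had 22 counts in complete medium and 3 without methionine. Apip, of methionine salvage, was 3.11-fold lower (2.29 to 4.26). Ahcy, which encodes the enzyme that hydrolyses S-adenosylhomocysteine, was 1.65-fold lower (1.57 to 1.72), and Mtap, which starts methionine salvage, was 1.43-fold lower (1.34 to 1.53).

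The amino acid response list, targets of the GCN2-ATF4-CHOP pathway that answers uncharged tRNA, went both ways. Of 27 measured members, 8 were at least 1.5-fold higher and 8 at least 1.5-fold lower, and the median of -0.26 lay at percentile 0.26 while the mean was close to 0. The range of the median by resampling members was -0.50 to 0.35. At 2-fold, 5 were higher and 2 lower. The higher members included Ddit3, which encodes CHOP (chromosome 10, 127290774 to 127296288, plus strand), from 332 to 2568 counts, and Atf5 (chromosome 7, 44812256 to 44816658, minus strand), from 666 to 4762 counts. Atf4 itself was 1.78-fold higher (1.73 to 1.83), Trib3 2.40-fold (2.25 to 2.55) and Ppp1r15a, which encodes GADD34, 3.20-fold (2.95 to 3.48). Asns, the asparagine synthetase gene, was 1.60-fold lower (1.53 to 1.67). Phgdh and Psph, of serine synthesis, were 1.83-fold and 1.91-fold lower. Vldlr was 6.72-fold lower (4.35 to 10.8), from 126 to 25 counts. Chac1, which encodes a glutathione-degrading enzyme, was 1.27-fold higher (1.11 to 1.46). Ddit3 and Atf5 overlap Mars and Nup62 on the opposite strand. Of the 19 measured amino acid transporter genes, none was at least 1.5-fold higher and 2 were at least 1.5-fold lower, among them Slc43a1 at 3.46-fold (2.42 to 5.01); the list median was 0.15, at percentile 80.2. Of the 20 cytosolic aminoacyl-tRNA synthetase genes, 1 was higher and 2 lower by that measure, with a median of -0.05 at percentile 22.8; Aars was 1.55-fold higher (1.51 to 1.60) and Vars 1.58-fold lower (1.54 to 1.63).

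**Figure D2:**
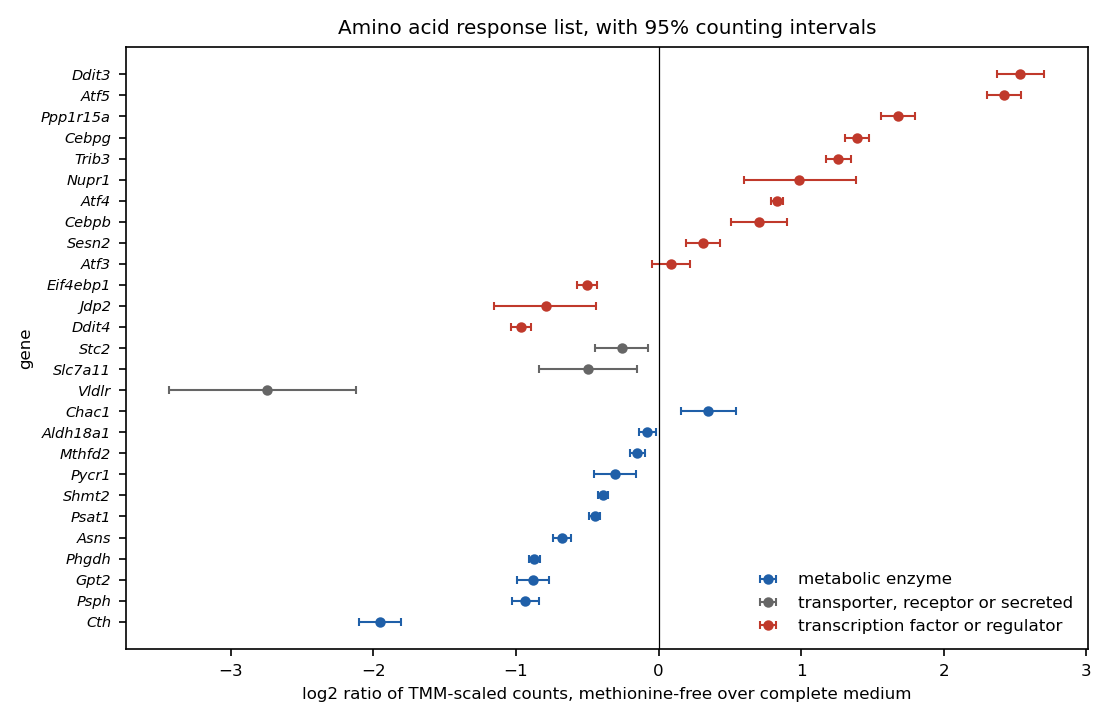
Ratio of TMM-scaled counts, methionine-free over complete medium, on a log2 axis for the 27 measured genes of the amino acid response list, with bars for the 95% counting interval of the 1 library per medium and colours for the kind of protein encoded. Ddit3 and Atf5 lie at 2.53 and 2.42 and Cth at -1.95.

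Cholesterol synthesis and glycolysis genes lay lower without methionine. Of 24 measured members of the cholesterol synthesis list, 19 were at least 1.5-fold lower and none at least 1.5-fold higher, with a median of -1.08 at percentile 0. Acat2, an acetyl-CoA acetyltransferase gene, was 3.51-fold lower (3.10 to 3.99) and Stard4, which encodes a sterol transfer protein, 3.39-fold (3.13 to 3.67). In the glycolysis list, 17 of 24 measured members were at least 1.5-fold lower, 6 of them at least 2-fold, and none higher, with a median of -0.67 at percentile 0. Pfkm, a phosphofructokinase gene, was 4.10-fold lower (3.47 to 4.86), and the glucose transporter gene Slc2a3 2.88-fold (2.74 to 3.02). The abundant transcript of the pyruvate kinase gene Pkm went from 4523 to 2292 CPM and that of Ldha, which encodes lactate dehydrogenase A, from 3836 to 2415 CPM. Aldoa was counted under a pair of neighbouring gene identifiers, with 32102 and 33376 counts under the main one and 24 and 5 under the other. Both are among the 24 members. The identifier with few counts is among the 17 lower members and the 6 at least 2-fold lower, while the main one was 1.28-fold lower. Gapdh, with 780 and 585 counts, and Fdps, with 55 and 22, have processed pseudogenes that could take their reads, so both are uncertain.

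Fads2 and Scd1, both fatty acid desaturase genes, were also among the 12 lowest genes. Fads2 (ENSMUSG00000024665, chromosome 19, 10062765 to 10101746, minus strand) had 201 counts in complete medium and 0 without methionine, which makes it at least 89.4-fold lower against a floor of 3 counts; the lower end of its 95% counting interval, which also holds the error of the 201 counts, was 72.0-fold. Scd1, the stearoyl-CoA desaturase gene, was 48.8-fold lower (25.4 to 108), from 329 to 9 counts. The hypoxia list of HIF1 targets shares Pdk1 with the glycolysis list. Of its 18 measured members, 9 were at least 1.5-fold lower and 3 higher. The list median of -0.46 lay at percentile 0.01, but its range by resampling members, -0.83 to 0.25, held 0. P4ha2, of collagen prolyl hydroxylation, was 4.72-fold lower (3.61 to 6.23) and Egln3, an oxygen-sensing prolyl hydroxylase gene, 2.60-fold (2.5 to 2.69). In the NRF2 and antioxidant list, 11 of 29 were lower and 3 higher, with a median of -0.38 at percentile 0.03; Gpx4, which encodes the lipid peroxide-reducing glutathione peroxidase, was 2.04-fold lower (1.89 to 2.2), and Gsto1 2.33-fold higher (2.14 to 2.54). Of 78 nuclear genes of oxidative phosphorylation, 14 were lower and 1 higher, with a median of -0.25 at percentile 0; Ndufa12 was 2.88-fold lower (2.54 to 3.29). Of 12 mitochondrially encoded genes, 3 were lower and 1 higher, with a median of -0.10 at percentile 18.5, and mt-Co1 was 1.54-fold lower (1.52 to 1.55). At 2-fold, 3 hypoxia genes were lower and 1 higher, 3 NRF2 and antioxidant genes lower and 1 higher, 1 nuclear oxidative phosphorylation gene lower and none higher, and no mitochondrially encoded gene was past the threshold.

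**Figure D3:**
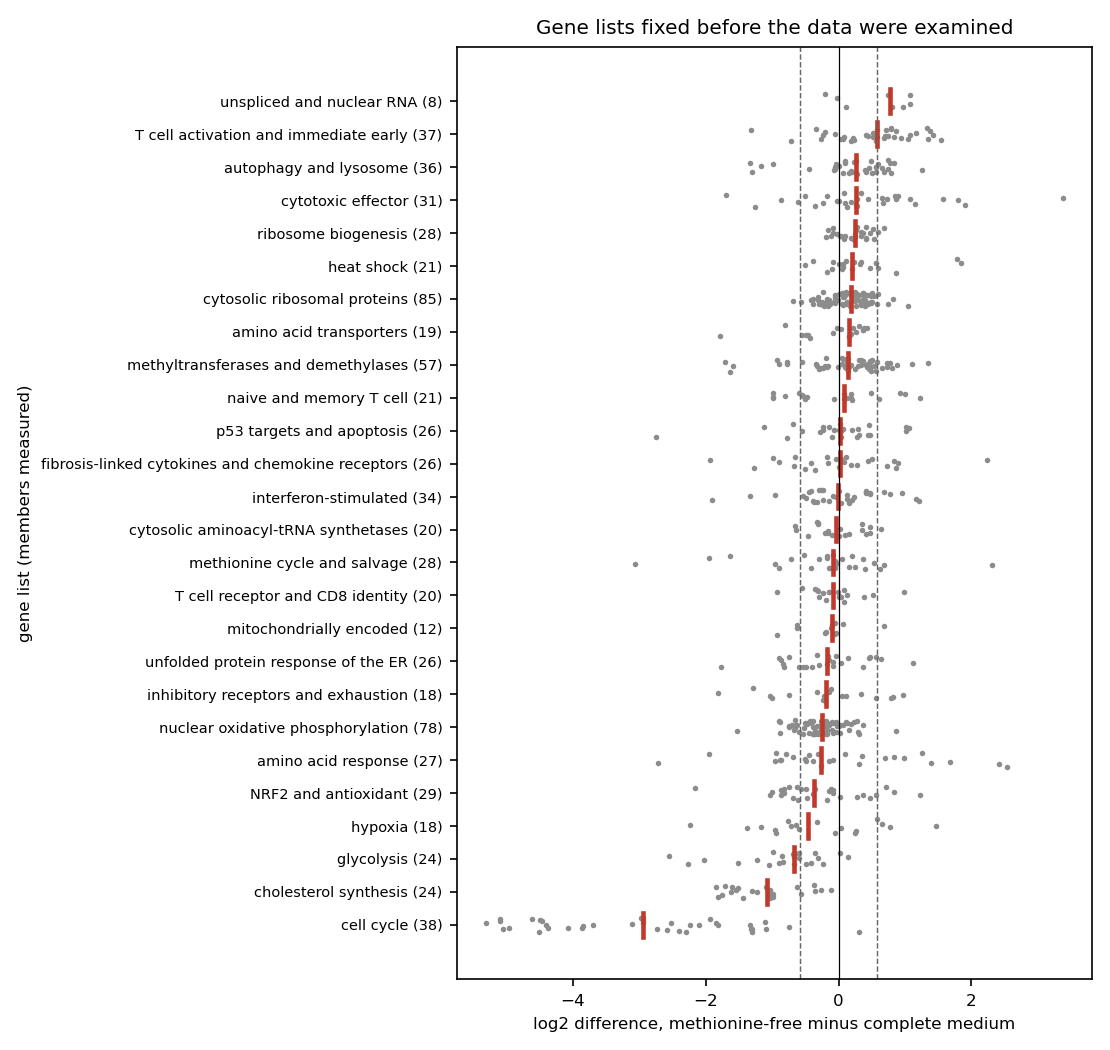
Log2 differences, methionine-free minus complete medium, of the measured members (grey points, spread vertically at random) of 26 gene lists, with the list median as a red bar and 1.5-fold marked by dashed lines. Medians run from -2.94 for the cell cycle list to 0.77 for the list fixed for long nuclear RNAs. The members of that last list past 1.5-fold are spliced hosts of small RNAs.

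T cell activation genes lay higher as a list, but not in every member. Of 37 measured members of the activation and immediate early list, 17 were at least 1.5-fold higher, 2 lower and 18 between. The median was 0.58, at percentile 100. Cd69, an early activation marker, was 2.90-fold higher (2.77 to 3.04), Rel, which encodes the NF-kB subunit c-Rel, 2.68-fold (2.51 to 2.86), Nfkbia 2.60-fold (2.46 to 2.74) and Tnfaip3 2.54-fold (2.41 to 2.68). The last 2 encode NF-kB inhibitors. Il2ra, the interleukin-2 receptor alpha chain gene, was at 1040 CPM in complete medium and 1008 CPM without methionine. In the cytotoxic effector list, 12 of 31 members were higher and 4 lower, with a median of 0.27 at percentile 97.2. Il2 had 3 and 47 counts, a ratio of 11.7 (3.78 to 59.0), the chemokine gene Ccl4 was 3.47-fold higher (2.87 to 4.22) and Xcl1 3.80-fold (2.77 to 5.31). Ifng, at 264 and 492 CPM, was 1.87-fold higher (1.80 to 1.94). Tnfsf10, which encodes the death ligand TRAIL, was 3.23-fold lower (2.70 to 3.87), and Gzmb, the granzyme B gene, was 2.39-fold lower (2.35 to 2.43), from 2621 to 1095 CPM. In the inhibitory receptor and exhaustion list, 5 of 18 were lower and 3 higher, with a median of -0.18 at percentile 11.5; Tigit was 3.55-fold lower (2.88 to 4.41) and Ctla4 1.99-fold (1.91 to 2.08). At 2-fold, 8 activation genes were higher and 1 lower, 6 cytotoxic effector genes higher and 2 lower, and no inhibitory receptor gene higher and 3 lower.

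Cd8a went from 664 to 527 CPM and Cd8b1 from 398 to 358 CPM. Of 20 measured genes of the T cell receptor complex and CD8, 1 was at least 1.5-fold higher and 1 at least 1.5-fold lower, the latter being the adapter gene Lat at 1.91-fold (1.82 to 2.0); the median was -0.08, at percentile 12.4. In the naive and memory list, 4 of 21 were higher and 5 lower, with a median of 0.08 at percentile 59.6; Klf3 was 2.34-fold higher (2.06 to 2.66) and Id3 1.97-fold lower (1.64 to 2.38). In the list of fibrosis-linked cytokines and chemokine receptors, chosen because the series concerns liver fibrosis, 5 of 26 were higher and 6 lower, with a median of 0.02 at percentile 48.3. Csf2, which encodes GM-CSF, was 4.78-fold higher (3.33 to 7.03), from 35 to 223 counts; Il13 was 2.46-fold lower (1.57 to 3.91), and Il10, at 24 and 8 counts, 4.0-fold lower (1.74 to 10.3). Tgfb1 went from 193 to 170 CPM. At 2-fold, none of the T cell receptor and CD8 list was past the threshold, 1 naive and memory gene was higher and none lower, and 1 gene of the fibrosis-linked list was higher and 2 lower.

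Trnp1, named in the title of the series (ENSMUSG00000056596, chromosome 4, 133491100 to 133498550, minus strand), had 2 counts in the complete-medium library and 11 in the methionine-free library, or 0.136 and 0.561 CPM. The ratio of 4.12 had an interval of 0.900 to 38.3, so a difference was not detectable at this depth, and the gene lies under the minimum mean of 10 counts.

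The gene with the highest log2 difference among those with a mean of at least 50 counts was Il23a (ENSMUSG00000025383, chromosome 10, 128296139 to 128298752, minus strand), which encodes the p19 subunit of interleukin-23. It had 5 counts in complete medium and 818 without methionine, a 123-fold difference (52.3 to 379). Trat1, which encodes a transmembrane adapter of the T cell receptor, was 9.24-fold higher (7.65 to 11.2), and Acot2, a mitochondrial acyl-CoA thioesterase gene, 7.12-fold (5.98 to 8.53). Zbtb7b, which encodes ThPOK, a transcription factor of the CD4+ lineage, was 6.29-fold higher (5.31 to 7.50), while Cd4 had 9 and 11 counts. Cxcl16, the gene of the ligand of CXCR6, was 5.78-fold higher (3.76 to 9.25). Srp54b was 11-fold higher (8.59 to 14.2), but its near-identical neighbours Srp54a, with 139 and 163 counts, and Srp54c, with 428 and 497, could share its reads, so this gene is uncertain. The other genes among the 12 highest, Adgrg3, Rn7sk, Avil, Adgrg6 and Tas1r3, were between 6.05-fold and 11.7-fold higher on at most 22 counts in complete medium. Avil, Tas1r3, Adgrg6, Zbtb7b and Cxcl16 overlap other genes with counts on the opposite strand, as do Pfkm, Gsto1, Nsd2 and Kdm2b. Among the 12 lowest, BC030867, Ccdc141 and Ankle1 were 55.4-fold, 50.7-fold and 42.5-fold lower.

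Of 57 measured methyltransferase and demethylase genes of histones, DNA and RNA, 8 were at least 1.5-fold higher and 7 at least 1.5-fold lower, with a median of 0.15 at percentile 90.9. At 2-fold, 2 were higher and 3 lower. The maintenance DNA methyltransferase gene Dnmt1 was 3.10-fold lower (2.99 to 3.21), from 678 to 219 CPM. The DNA demethylase gene Tet1 was 3.32-fold lower (2.22 to 5.06) and the histone H3 lysine methyltransferase gene Nsd2 3.0-fold (2.83 to 3.19). The cell cycle list was lower too, with a median of -2.94. Whether the lower methylation enzyme genes, Dnmt1 among them, are part of that difference was not tested. Kdm2b, a histone demethylase gene, was 2.55-fold higher (2.42 to 2.70), and Dnmt3a, a de novo DNA methyltransferase gene, 1.70-fold (1.61 to 1.80).

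Ribosomal protein genes lay slightly higher as a list, with a median of 0.19 at percentile 99.6, although 4 of 85 members were at least 1.5-fold higher and 1 lower; Rpl17 was 1.76-fold higher (1.71 to 1.82) and Rpl21 1.62-fold lower (1.54 to 1.70). Processed pseudogenes of these genes could share their reads. In the ribosome biogenesis list, 2 of 28 were higher and none lower, with a median of 0.25 at percentile 98.4, or 95.16 against random lists not matched on expression, and Rrs1 was 1.62-fold higher (1.53 to 1.71). In the autophagy and lysosome list, 9 of 36 were higher and 4 lower, with a median of 0.27 at percentile 98.5; Atg14, which encodes an autophagy initiation factor, was 2.38-fold higher (1.91 to 2.97), and Tfeb, a lysosomal transcription factor gene, 2.49-fold lower (1.91 to 3.26). In the list of ER unfolded protein response genes outside the PERK arm, 7 of 26 were lower and 2 higher, with a median of -0.17 at percentile 1.78. Under 3 other settings this list lay at percentiles 2.82, 4.435 and 7.73, inside the central 95%. Sdf2l1 was 3.42-fold lower (3.08 to 3.80) and the chaperone gene Dnajb9 2.17-fold higher (1.84 to 2.57). In the heat shock list, 4 of 21 were higher and none lower, with a median of 0.20 at percentile 90.4; the near-identical HSP70 genes Hspa1a and Hspa1b were 3.59-fold (2.59 to 5.09) and 3.44-fold (2.78 to 4.29) higher and could share reads. Of 26 p53 targets and BCL2 family genes, 3 were higher and 4 lower, with a median of 0.03 at percentile 38.5; the death receptor gene Fas was 2.02-fold higher (1.83 to 2.24). Of 34 interferon-stimulated genes, 5 were higher and 3 lower, with a median of -0.01 at percentile 36.6; Cxcl10 was 2.25-fold higher (1.88 to 2.70) and Dhx58 2.54-fold lower (1.85 to 3.52). At 2-fold, 1 autophagy and lysosome gene was higher and 3 lower, 1 ER unfolded protein response gene higher and 1 lower, 2 heat shock genes higher and none lower, and no ribosome biogenesis gene was past the threshold.

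Markers of other cell types were measured because a splenic CD8+ isolation can retain other cells. Of 12 measured B cell markers, 2 were at least 1.5-fold higher and 5 lower, with a median of -0.40 at percentile 6.51; the immunoglobulin gene Ighm was at 196 CPM in complete medium and 120 without methionine, and H2-Aa was 2.41-fold higher (2.04 to 2.85). With a mean of at least 100 counts 4 markers were left, and their median was 0.434. Of 8 markers of CD4+ and regulatory T cells, 3 were higher and 2 lower (median 0.31, percentile 90.2). Of 7 myeloid and dendritic cell markers, 3 were higher and none lower (median 0.56, percentile 96.7), with the cytokine receptor gene Flt3 3.38-fold higher (2.31 to 5.10), from 33 to 149 counts. Of 6 NK cell markers, 2 were higher and none lower (median 0.29, percentile 79.3). Of 4 red cell and platelet markers, 1 was higher and 2 lower (median -0.66, percentile 18.0), all on at most 34 counts in either library. Pecam1 and Col1a2 were the 2 measured stromal markers, 1 of them lower and 1 higher (median 0.05, too few for a percentile).

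RNAs that show the kind of library were also compared, because the labels name both a whole-RNA and an mRNA kit. Histone and small structural RNAs without a poly(A) tail summed to 95.8 CPM in complete medium and 68.7 CPM without methionine. Protein-coding genes held 97.6% of the counts in both libraries. Neither library thus held much RNA of this kind, though these values do not show which kit made which library. Of 32 measured, 9 were at least 1.5-fold higher and 15 lower, with a median of -0.39 at percentile 5.66; the replication-dependent histone gene Hist1h3c was 62.7-fold lower (16.9 to 525), from 94 to 2 counts, and the small nuclear RNA gene Rn7sk 7.84-fold higher (4.22 to 16.1), from 11 to 115 counts. Restricted to protein-coding genes with a named symbol, the 15 measured members had a median of -1.67. The cell cycle list was lower too, so lower replication-dependent histone genes cannot be read as a difference of kit. The cause was not tested. Of 8 measured members of the list fixed for long nuclear RNAs, 5 were higher and none lower, with a median of 0.77 at percentile 100. The 5, all spliced hosts of small RNAs, were Snhg1 at 2.11-fold (2.0 to 2.23), Snhg12, Snhg15, Mir17hg and Gas5, and 2 of them were past 2-fold. The other 3 had log2 differences of -0.02 for Malat1, 0.11 for Neat1 and -0.21 for Kcnq1ot1, so the list median does not describe nuclear RNA as a whole. Malat1 was at 95.7 and 94.4 CPM. Of the 32 fixed lists with enough members for a percentile, 8 lay below and 5 above the central 95% of their random lists. The ER unfolded protein response list lay inside it under 3 other settings and the ribosome biogenesis list under 1. The lists of cytotoxic effectors, myeloid markers, CD4+ T cell markers, B cell markers, methyltransferases and RNAs without a poly(A) tail lay outside it under other settings only. For some lists past either end, the range of the median by resampling members held 0. These were the hypoxia list (-0.83 to 0.25), the amino acid response list (-0.50 to 0.35) and the long nuclear RNA list (-0.02 to 1.02). Their percentiles therefore do not show that the members moved together.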

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

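The thinning of the deeper library, the removal of the GC content and length trend, and the lists without cell cycle members were chosen after seeing the data. The number of genes past 2-fold depended on the minimum count, the genes entering and the threshold. With a mean of at least 100 counts, 264 genes were higher and 576 lower; without a minimum, 3333 were higher and 4877 lower. The genes entering were 9522 and 21114 in place of 13041. The shares past 2-fold differed too, at 2.77% higher and 6.05% lower and at 15.8% higher and 23.1% lower, in place of 5.80% and 9.29%. The genes added without a minimum have a mean below 10 counts, where a few counts can make 2-fold, so they are not read as changed. How much of the difference between settings is counting error was not tested. Among protein-coding genes with a named symbol, 500 were higher and 967 lower. At 1.5-fold, 2050 genes were higher and 2346 lower, and at 4-fold 120 and 389. Of 64 numbers of list members past 1.5-fold, 45 differed by more than 1.5 times when counted at 2-fold. Under the other 6 settings of scaling, prior count, gene removal, thinning and GC content both numbers stayed within 1.5 times, from 670 to 776 higher and from 1162 to 1228 lower. No scaling moved the median of all genes by more than 0.1 on the log2 scale.

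List medians kept within the range expected from resampling their members in all but 2 cases. The B cell list had a median of 0.434 over 4 members with a mean of at least 100 counts, and the list without a poly(A) tail a median of -1.67 over 15 members among protein-coding genes; both lists held fewer members there. No list past either end of its random lists changed sign. The ER unfolded protein response list left the lowest 2.5% under 3 settings, at percentiles 2.82, 4.435 and 7.73, and the ribosome biogenesis list left the highest 2.5%, at percentile 95.16 against random lists not matched on expression. Cytotoxic effector genes reached percentile 97.63 to 98.74 under 3 settings and myeloid markers 97.955 to 98.74 under 4; CD4+ T cell markers reached 98.67 and 99.62 under the 2 other minimum counts. The list without a poly(A) tail lay at percentiles 0 to 0.2 under 3 settings and the B cell list at 2.31 against unmatched random lists. The methyltransferase list reached 99.2 after the GC content and length trend was removed. The cause was not tested. No named gene whose counting interval excluded a ratio of 1 changed direction under any setting. For named genes whose interval held 1, a change of direction was not looked for. After removal of the GC content and length trend, 33 of 156 named genes moved outside their counting interval. Trnp1 kept a log2 difference of 1.43 to 1.84. The authors' own fold change was not run because the table used here holds none, and no library could be left out in turn with 1 per medium. No paired analysis was possible because each medium has 1 library. Depth limits genes near 3 counts, such as Trnp1.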

Other observations

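The gene lists of this part, the roles within the amino acid response list, and the tests of other cell types, of MYC output and of culture differences were chosen after the result was seen, as was leaving the members named by the rule out of the fatty acid test. Genes of fatty acid synthesis and desaturation were lower without methionine, with 13 of 19 measured members at least 1.5-fold lower, none at least 1.5-fold higher and a median log2 difference of -0.86 at percentile 0 of matched random lists. The median is the same with Fads2, at 0 counts, set to its bound. Scd2, the abundant stearoyl-CoA desaturase gene of these cells, went from 800 to 54.6 CPM, 14.7-fold lower (13.8 to 15.6). Fads1, the partner of Fads2 in polyunsaturated fatty acid synthesis, was 2.42-fold lower (2.15 to 2.72), and Fasn, the fatty acid synthase gene, 1.44-fold (1.40 to 1.48). In purine and pyrimidine synthesis, 7 of 19 genes were at least 1.5-fold lower and none higher (median -0.35, percentile 0.13), with Dctpp1 2.21-fold lower (2.01 to 2.43) and Cad 1.58-fold (1.53 to 1.63).

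Targets and feedback regulators of NF-kB were higher, with 20 of 24 at least 1.5-fold higher, none lower and a median of 1.06 at percentile 100; the list was drawn up around members already seen to be high, so its direction is not independent evidence. Cd83, an activation marker, was 5.43-fold higher (4.86 to 6.07), Icam1 2.42-fold (2.30 to 2.55) and Nfkb2 2.40-fold (2.31 to 2.49). Of 11 ligands of the tumour necrosis factor family, 5 were higher and 1 lower (median 0.27, percentile 88.5). Tnfsf11, which encodes RANKL, was 4.38-fold higher (3.54 to 5.48), Tnfsf8, which encodes CD30 ligand, 3.67-fold (3.37 to 4.0) and Cd70 4.04-fold (2.21 to 7.95). Of 16 genes of MHC class I presentation, 2 were higher and 3 lower (median -0.05, percentile 22.5). H2-K1 was 1.70-fold higher (1.68 to 1.73), and the immunoproteasome gene Psmb10 was 1.93-fold lower (1.75 to 2.12).

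The lower level of cell cycle genes was weighed against technical explanations. After the trend with GC content and transcript length was removed, the list median was -2.93, so that trend does not account for it. Dividing B cells retained in complete medium stay open: the 12 measured B cell markers had a median of -0.40 (-1.01 to 0.26 by resampling members), and Ighm, at 196 and 120 CPM, lay above the 121 CPM of the median cell cycle gene there, while Cd74 went from 37.4 to 69.2 CPM. Of the other types' markers in complete medium, Eomes, which CD8+ T cells also express, was at 159 CPM, Pecam1 at 35.5, Ctss at 28.2 and Itga2b at 2.04 CPM; of CD4+ T cell markers, Ctla4, which activated CD8+ T cells also express, was at 394 CPM, and Cd4 itself at 0.613 CPM. With 1 library per medium, an effect of the medium and any other difference between the 2 cultures cannot be told apart, and the medium stays open as an untested explanation.

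Members of the amino acid response list differed in part by role: 13 regulators had a median of 0.83, 11 metabolic enzymes -0.45 and the 3 others, Vldlr, Slc7a11 and Stc2, -0.49. The roles do not divide the list cleanly, since the regulators Ddit4 and Jdp2 were at least 1.5-fold lower and the enzyme gene Chac1 lay above 0; regulators and enzymes differed by 1.28, and by 1.31 after the GC content and length trend was removed. Lower output of MYC, which drives ribosome biogenesis and metabolic enzymes, would lower the ribosome biogenesis list. The median of that list was 0.25, and Myc itself was 1.62-fold higher (1.59 to 1.66). Lists of metabolic enzymes went the other way, with medians of -0.35 for purine and pyrimidine synthesis and -0.67 for glycolysis. The ribosome biogenesis list alone therefore does not settle whether MYC output was lower. A candidate explanation is lower metabolic transcription dependent on mTORC1, a kinase that drives lipid synthesis genes through SREBP. The 16 fatty acid genes outside the rule for named genes, Scd2, Fads1 and Fasn among them, had a median of -0.73 at percentile 0. The hypothesis needs such a low value, but the value could be foreseen. Fads2, Scd1 and the cholesterol synthesis list, with a median of -1.08, had already been seen to lie lower. Lower SREBP activity from another source would also give the same value. These genes therefore do not decide why the enzymes of the amino acid response list lay lower.

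Several genes known from dendritic cells were higher without methionine, among them Flt3, Zbtb46 at 3.49-fold (2.73 to 4.53), Ciita at 3.83-fold (2.32 to 6.63), Cd83 and Il23a. Dendritic cells retained in that library, which a CD8+ isolation would be meant to remove, would raise their abundant transcripts together. A list median of at least 1 on the log2 scale was set beforehand as the mark of this. The size of such a rise would depend on how many cells were retained and how much of each transcript other cells supply. The 18 measured members of a list of such transcripts, 10 of whose genes are also in another list, had a median of 0.23 (-0.30 to 0.77 by resampling members), with 7 of the 18 at least 1.5-fold higher, 3 at least 1.5-fold lower and 8 at or below 0. Of the higher members, Tmem176b, at 7 and 51 counts, had a log2 difference of 2.38, H2-Aa 1.27, Sirpa 1.04, H2-Eb1 0.92 and Cd74 0.89, while Cst3 went from 49.0 to 58.5 CPM, H2-Ab1 from 22.9 to 22.7 CPM, Tyrobp had 3 and 6 counts, Lyz2 4 and 4, and Fcer1g 6 and 1. The list median fell short of the mark set beforehand, but a smaller share of retained dendritic cells is not excluded by it. Expression by the T cells themselves also stays open and was not tested.

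Hosts of small nucleolar RNAs were also higher, and the hypothesis that this holds for hosts outside the fixed list was tested on 10 further genes. Their median log2 difference was 0.47 (-0.15 to 0.65 by resampling members), at percentile 98.74; 3 of the 10 were at least 1.5-fold higher, among them Zfas1 at 2.23-fold (2.11 to 2.36), and 1 lower, Snhg14 at -0.96. The list first held a pseudogene by mistake in place of Dancr and then lay at percentile 93.8; because the correction followed the first value and moves it past the central 95% of random lists, the test does not settle the question. Less nonsense-mediated decay, which degrades these RNAs, may be a source. The transcripts of 10 decay factors, which the pathway itself limits, lay at percentile 88.16 with a median of 0.25, between the bounds set beforehand. A general increase of terminal oligopyrimidine mRNAs, the class these hosts belong to, would raise 23 such mRNAs outside ribosomal proteins, whose median was -0.050 (-0.19 to 0.21 by resampling members) at percentile 24.0. Ribosomal protein genes, of the same class, lay at percentile 99.6 but with a median of 0.19 (0.10 to 0.26), so such an increase does not account for the whole difference of the hosts, and a smaller contribution stays open.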
